A study of Mus musculus with 16 samples.

How the data were processed

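Polyadenylated RNA was sequenced from cultured dermal fibroblasts (DF, the connective tissue cells of the skin) and aortic vascular smooth muscle cells (VSMC) of 4 mice. Per the labels, 2 mice were Stat1+/- and 2 were Stat1-/-. Cells at passage 2 were held in low serum for 24 hours and then received PDGF-BB, a growth factor for mesenchymal cells, at 30 ng/mL for 1 hour, or nothing. Serum during this time is given as 0.05% in the protocol and as 0.1% in the design text. Genotype, cell type and treatment make 8 groups of 2 libraries, 16 in all. The labels call these Stat1+/- mice "wt", and no Stat1+/+ group is listed.

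The deposited table gives, per the labels and its column names, raw counts and FPKM (fragments scaled to transcript length and library size) for each library and each of 23200 RefSeq transcripts. The notes of the authors name FastQC, HISAT2, featureCounts and DESeq2 with the mm10 genome build and no versions. The tool and lengths behind the authors' FPKM are not stated. All main results rest on the deposited counts, which are whole numbers. FPKM entered 1 alternative and gave the transcript lengths for 1 test of zinc finger genes.

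RefSeq gene tables named 22755 rows and GENCODE M21 a further 140. The 305 rows without a name hold 1.45% of all counts, and 428 symbols have more than 1 row. Rows were tested one by one. Total counts ranged from 25204151 to 32421617 per library. Counts were made without molecular identifiers, so their counting error is a lower limit of the error. Between mice of a group, the variance was 13 to 102 times what counting alone gives (chi-square per degree of freedom, a mean over genes). Levels are given as CPM (counts scaled to the library total) with normalisation factors, as mean ± SD (n = 2).

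Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr by group (minimum count 10, minimum total 15, smallest group 2), robust estimateDisp, robust glmQLFit with legacy=FALSE set explicitly, and the quasi-likelihood F test. One fit of the 16 libraries with 8 group means had 8 residual degrees of freedom and a median prior of 2.92. It tested 14477 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 in a comparison are called, with no minimum fold. All p-values are two-sided. The fit gives the log2 fold change. The standard error (SE) printed after ± is an approximation: the absolute log2 fold change divided by the square root of the F statistic.

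There were 12 comparisons: PDGF-BB against none in each genotype and cell type, the genotype by PDGF-BB interaction in each cell type, Stat1-/- against Stat1+/- in each cell type and treatment, VSMC against DF in untreated cells, and the cell type by PDGF-BB interaction averaged over genotypes. Treated and untreated libraries of a culture come from the same mouse, which the numbering in the titles gives. To check this pairing, deviations of each library from its group mean were correlated across 10326 genes. The correlation was 0.673 and 0.656 in DF and 0.874 and 0.898 in VSMC. The notes state no design, so the main comparisons use group means. A fit with the culture as a block (4 residual degrees of freedom) is printed beside them. The group means leave the pairing out, and for PDGF-BB and its interactions they called fewer genes than the blocked fit. For genotype, the 8 residual degrees of freedom count libraries of the same culture as independent, although they deviated together. Each gene also has a single spread for both cell types, while mice of a group differed more in VSMC (chi-square per degree of freedom 52.9 to 102) than in DF (13 to 22.9). The p-values for genotype, above all in VSMC, may therefore be too small. Cells of both types from 1 mouse correlated at 0.082 to 0.147. Each culture holds 1 cell type, so the blocked fit of untreated VSMC against DF used the mouse as the block. Tallies over comparisons count it with the fits blocked on the culture.

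The 22 gene lists were immediate early genes, MAPK and receptor feedback inhibitors, inflammatory and NF-kB target genes, growth factors, PDGF receptors and co-receptors, type I interferon-stimulated genes, interferon gamma and MHC class I genes, JAK-STAT components and feedback, SRF and MRTF cytoskeletal targets, FoxO targets repressed by growth factors, sterol synthesis genes, mitotic genes, extracellular matrix genes, smooth muscle contractile markers, dermal fibroblast markers, heat shock genes, and markers of endothelial cells, leukocytes, keratinocytes, skeletal muscle and myoblasts, Schwann cells and melanocytes, and adipocytes. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and p-values were adjusted over all 264 tests (22 lists by 12 comparisons). A list is called when this p is below 0.05. Camera with an estimated correlation is given beside it where that call ends. List tests with a block used the preset correlation alone. Members called when p-values are adjusted over the list alone are counted too. In 49 of the 264 tests the median or mean of the list had the opposite sign to the test, and 0 of these were called. Of the list members, 9 have no row under their symbol in the table and were not tested.

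Comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule always names Stat1, Pdgfra and Pdgfrb. Per comparison it takes up to 8 genes higher and 8 lower with the largest change among called genes with a mean of at least 5 CPM and the same direction in both mice, up to 10 genes of smallest adjusted p for an interaction, and per list up to 4 called members with the largest change or, where none is called, the 2 with the smallest p. Predicted genes and pseudogenes were counted but are not named. Genes outside this rule are named as such.

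Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter at a mean of 5 CPM, the legacy quasi-likelihood method, a fit of 1 cell type, the culture as a block, and leaving out each library. Leaving out a library leaves an arm with 1 library, which is assumed to vary like the other groups. A further pair was chosen after seeing the data: leaving out 7 rows listed at 0 in every library of some group although their mean count elsewhere was above 2000, and limma on log2(FPKM + 0.5). Correlations between responses are across genes, which are not independent replicates. Calls near Stat1 were counted within 10 Mb and tested with Fisher's exact test. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

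The procedure was tested on simulated data with 200 changed genes. These were drawn from genes with a mean of at least 5 CPM outside all lists, and the immediate early genes were changed 2 fold besides. For PDGF-BB in Stat1+/- DF it called 25.4%, 83.6% and 93.9% of genes changed 1.5, 2 and 4 fold, and 3.9% of its calls were unchanged genes. For the interaction in DF it called 6%, 41.8% and 83.3%, with 7% false calls. With the culture as a block, false calls made up 6.3% and 11.3%. The simulated counts had no culture effect, whereas libraries of a real culture deviated together. The rates with and without the block therefore need not hold for the real data, nor for scarcer genes or members of the lists. No sample was left out.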

Results

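RNA was measured by sequencing in 16 libraries: DF and VSMC from 2 Stat1+/- and 2 Stat1-/- mice, each untreated or treated with PDGF-BB for 1 hour. The 8 groups hold 2 libraries each, from mice numbered as replicates 0 and 1 (Stat1+/-) and 2 and 3 (Stat1-/-). Total counts per library lay between 25204151 and 32421617. STAT1 is the transcription factor through which interferons act. PDGF-BB is a growth factor that signals through the receptors encoded by Pdgfra and Pdgfrb. The title of the series puts the question: which genes PDGF-BB induces in cells that lack Stat1. All levels below are CPM as mean ± SD (n = 2 mice), and adjusted p-values are from edgeR unless a list test is named.

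Stat1 (NM_009283, chromosome 1, 52119438 to 52161865 in mm10) was nearly absent from the Stat1-/- libraries. Untreated DF held 45.1 ± 7.76 CPM in Stat1+/- and 0.261 ± 0.143 in Stat1-/- cells, and untreated VSMC 31.1 ± 7.91 and 0.137 ± 0.042. Over treated and untreated libraries together, the Stat1-/- level was 0.512% of the Stat1+/- level in DF and 0.565% in VSMC. The log2 difference was -7.42 ± 0.39 in untreated DF (adjusted p = 1.51e-05), -7.74 ± 0.39 in treated DF (2.83e-06), -7.81 ± 0.45 in untreated VSMC (3.74e-05) and -7.13 ± 0.42 in treated VSMC (4.86e-05), lower in 2 of 2 mice each time. Stat1 did not pass the test with PDGF-BB in any group: in Stat1+/- DF it stood at 61.5 ± 4.51 CPM treated against 45.1 ± 7.76 untreated (log2 fold change 0.45 ± 0.23, adjusted p = 0.337). With the culture as a block this difference passed (adjusted p = 5.77e-05, range over its alternatives 5.77e-05 to 0.8). The PDGF receptor gene Pdgfrb lay between 905 ± 89.3 and 1136 ± 74.3 CPM in all 8 groups and was called in 0 of the 12 comparisons by edgeR.

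Called genes that rose with PDGF-BB in Stat1+/- DF within 1 hour included members of the immediate early, cytokine and interferon-type lists. Errfi1, a feedback inhibitor of EGF receptors, rose from 43.8 ± 2.87 to 942 ± 68.7 CPM (log2 fold change 4.43 ± 0.13, adjusted p = 2.1e-08). Arc, an immediate early gene, rose from 1.33 ± 0.201 to 72.4 ± 7.69 CPM (5.77 ± 0.29, 1.42e-06). The hyaluronan synthase Has1 rose from 0.859 ± 0.245 to 70.6 ± 11.5 CPM and the inhibitor of cytokine signalling Socs3 from 7.82 ± 0.745 to 401 ± 55.3 CPM (adjusted p = 0.000112 and 0.000157). The largest falls were in zinc finger genes such as Zfp799, from 11.2 ± 0.774 to 1.94 ± 0.812 CPM (-2.52 ± 0.24, 8.25e-05), and in Zfp759, Zfp955b, Zfp113 and Zfp955a, together with Fam126b (-1.78 ± 0.13), the histone methyltransferase gene Setd1b (-1.69 ± 0.21) and the phosphatase subunit gene Ppp1r3d (-1.74 ± 0.25). In all, 666 genes rose and 564 fell, of which 285 and 194 changed at least 2 fold.

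Of 31 immediate early genes, 27 rose and 4 were not called in Stat1+/- DF (camera adjusted p = 4.85e-109, 27 adjusted over the list alone). They included the transcription factor genes Egr3 (5.46 ± 0.541 to 228 ± 1.68 CPM) and Nr4a3 (7.48 ± 0.139 to 215 ± 13.4 CPM). Among 16 MAPK and receptor feedback inhibitors 9 rose, 1 fell and 6 were not called (1.09e-27, 9 higher and 2 lower over the list alone). The member that fell was Dusp7, an ERK phosphatase gene. The ERK phosphatase gene Dusp5 (log2 fold change 5.43 ± 0.42), Spry4 (2.51 ± 0.21) and Dusp4 (1.73 ± 0.11) were among those that rose. Inflammatory and NF-kB target genes rose in 10 of 22, with 1 lower and 11 not called (5.31e-09, 15 higher and 1 lower over the list alone, adjusted p = 0.232 with an estimated correlation). The cytokine gene Il6 went from 0.609 ± 0.242 to 37.6 ± 17.6 CPM and the prostaglandin synthase gene Ptgs2 from 52.5 ± 5.36 to 773 ± 47.4 CPM. The member that fell was Nfkbia, the inhibitor of NF-kB (-1.20 ± 0.11). Growth factor genes rose in 9 of 27 with 18 not called (2.08e-07, 9 over the list alone), among them the EGF-type ligand genes Areg (0.187 ± 0.044 to 10.8 ± 1.76 CPM) and Ereg (10.4 ± 5.34 to 71.1 ± 16.7 CPM).

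Type I interferon-stimulated genes were higher with PDGF-BB in 15 of 41 in Stat1+/- DF, with 0 lower and 26 not called (camera adjusted p = 9.5e-12, 20 over the list alone, adjusted p = 0.489 with an estimated correlation). The antiviral genes Rsad2 and Mx2 rose from 6.22 ± 3.23 to 92.2 ± 48.3 CPM and from 5.68 ± 2.68 to 59.2 ± 24.9 CPM (adjusted p = 0.000183 and 3.7e-05). Interferon gamma and MHC class I genes were higher in 14 of 27, with 13 not called (3.79e-16, 17 over the list alone, adjusted p = 0.156 with an estimated correlation). The transcription factor gene Irf1 rose from 18.3 ± 1.18 to 180 ± 59 CPM (3.29 ± 0.49, 0.00221), the GTPase gene Iigp1 from 17.2 ± 6.39 to 224 ± 107 CPM and the signalling inhibitor gene Socs1 from 1.87 ± 0.004 to 32.7 ± 0.53 CPM. JAK-STAT components and feedback genes rose in 9 of 19, fell in 2 and were not called in 8 (1.43e-10, 10 higher and 2 lower over the list alone), with Cish from 2.25 ± 0.039 to 80.3 ± 24 CPM. The members that fell were Bcl6, a transcriptional repressor gene, and Pias1, an inhibitor of activated STAT1. Dusp7, Bcl6 and Pias1 were named after their values were seen.

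FoxO targets repressed by growth factors fell in 5 of 15 with 10 not called in Stat1+/- DF (camera adjusted p = 0.000271, 1 higher and 7 lower over the list alone, adjusted p = 0.0651 with an estimated correlation). The cyclin gene Ccng2 fell from 51.8 ± 2.05 to 23.5 ± 0.454 CPM. Sterol synthesis genes rose in 4 of 20 with 16 not called (0.000613, 5 over the list alone, adjusted p = 0.831 with an estimated correlation), led by Hmgcr, the rate-limiting enzyme of cholesterol synthesis (391 ± 33.3 to 822 ± 102 CPM). Heat shock genes rose in 2 of 10 with 8 not called (1.37e-06, 4 over the list alone), Dnajb1 from 51.4 ± 2.65 to 155 ± 5.56 CPM and Bag3 from 146 ± 4.91 to 230 ± 17.1 CPM. SRF and MRTF cytoskeletal targets (0 of 19 called by edgeR), mitotic genes (0 of 20), PDGF receptors and co-receptors (0 of 5), extracellular matrix genes (0 of 21) and the lists of cell type markers had no list call here (camera adjusted p of 0.49 or above). DESeq2 called 1515 genes against 1230. The same comparison called 4138 genes (2332 higher, 1806 lower) with the culture as a block, 1890 with DF alone in the fit and 742 with limma on FPKM. It called 570 and 595 without untreated Stat1+/- DF replicate 0 or 1, and 640 and 773 without treated Stat1+/- DF replicate 0 or 1.

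**Figure D1:**
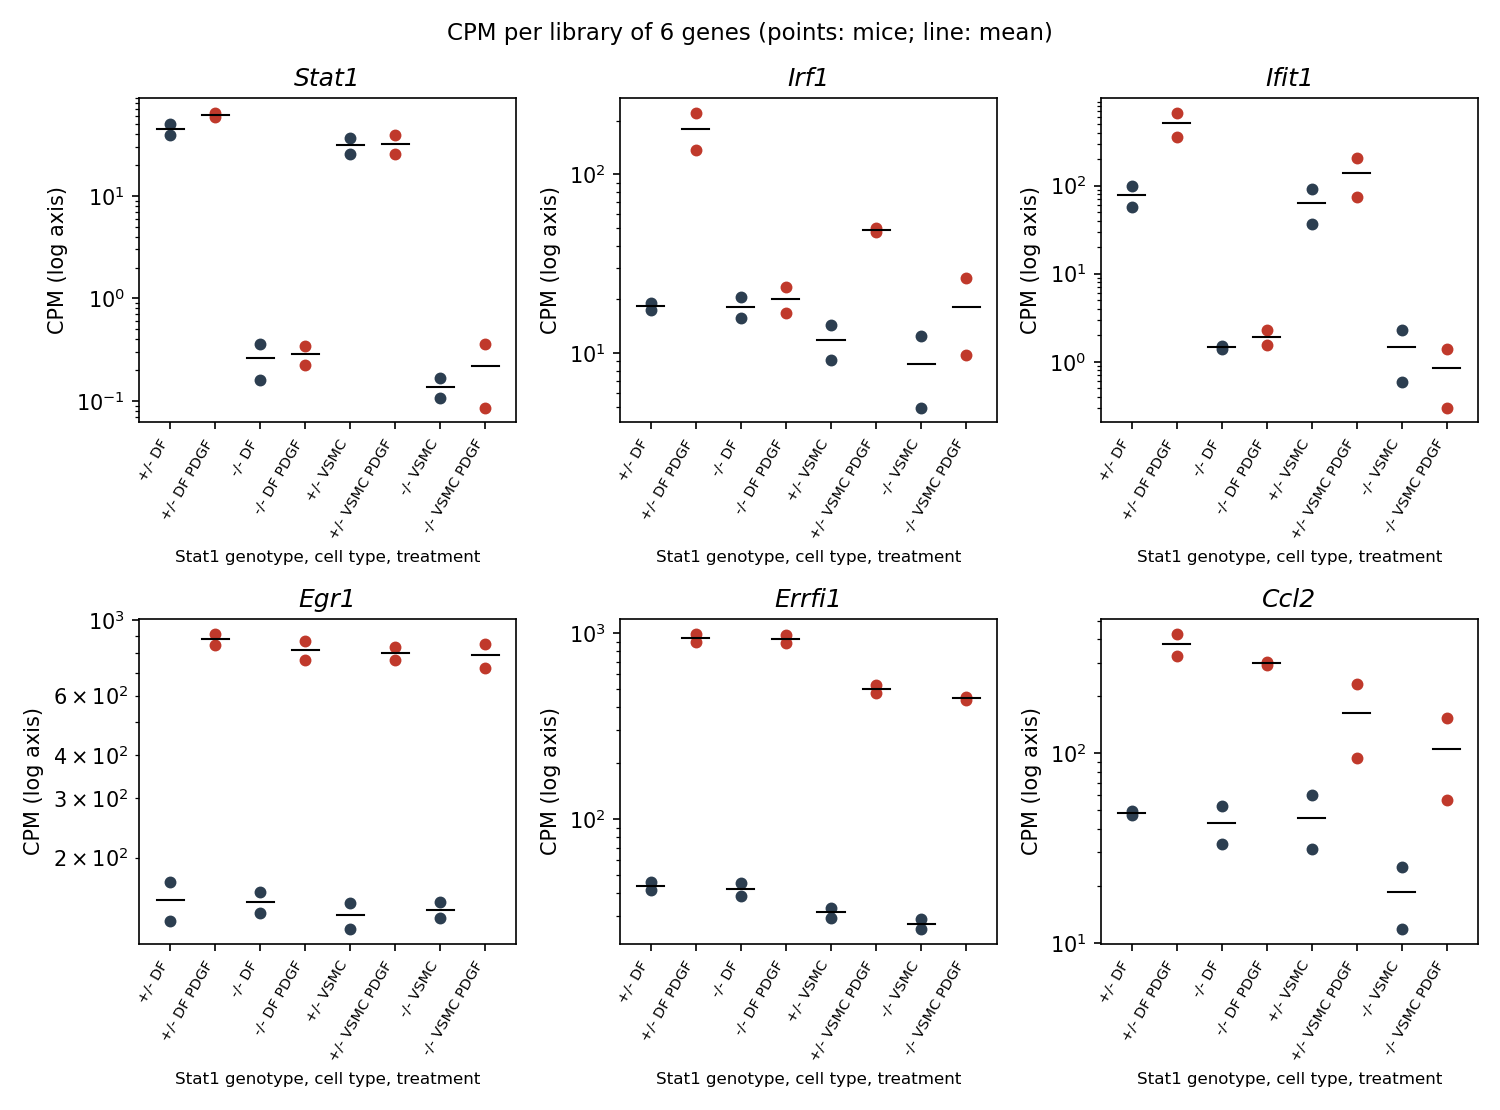
CPM of 6 genes in each library (log axis), with points for mice, lines for group means, blue for untreated and red for PDGF-BB. Errfi1 and Egr1 were higher with PDGF-BB in each cell type and genotype, whereas Irf1 reached 180 CPM in treated Stat1+/- DF and 20.2 CPM in treated Stat1-/- DF.

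In Stat1-/- DF members of the growth factor and inflammatory lists were called higher as well, and 3 of the 68 interferon-type genes were. Errfi1 rose from 41.9 ± 4.99 to 929 ± 67 CPM (log2 fold change 4.47 ± 0.13, adjusted p = 1.95e-08), Arc from 1.49 ± 0.261 to 86.4 ± 8.3 CPM (5.85 ± 0.29, 1.52e-06) and Has1 from 0.792 ± 0.143 to 58.9 ± 7.32 CPM (6.21 ± 0.60, 0.000175). Tac1, the precursor of substance P, rose from 0.208 ± 0.247 to 15.7 ± 1.25 CPM, and the microRNA gene Mir212 from 0.533 ± 0.103 to 21.1 ± 0.653 CPM. Zfp799 fell from 11.8 ± 0.185 to 2.86 ± 0.466 CPM, the insulin receptor adaptor gene Irs1 from 135 ± 7.73 to 45.8 ± 0.978 CPM and Ajuba, a scaffold protein gene, from 57.8 ± 1.1 to 20.1 ± 0.551 CPM. In all, 590 genes rose and 412 fell (234 and 142 by at least 2 fold).

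By list in Stat1-/- DF, 26 of 31 immediate early genes rose with 5 not called (camera adjusted p = 1.27e-107, 27 over the list alone), and 8 of 16 MAPK feedback inhibitors with 8 not called (1.68e-30, 10 higher and 1 lower over the list alone). Inflammatory genes rose in 8 of 22 with 1 lower and 13 not called (1.39e-08, 14 higher and 1 lower over the list alone, adjusted p = 0.251 with an estimated correlation), and Nfkbia was again the member that fell (-1.22 ± 0.11). Growth factor genes rose in 8 of 27 (1.31e-08, 10 over the list alone), JAK-STAT genes rose in 8 and fell in 2 of 19, Bcl6 and Pias1 (1.79e-09, 10 and 2 over the list alone) and heat shock genes rose in 2 of 10 (8.69e-06, 3 over the list alone). FoxO targets fell in 3 of 15 (0.000795, 1 higher and 8 lower over the list alone, adjusted p = 0.0899 with an estimated correlation). Sterol genes rose in 4 of 20 (0.000222, 6 over the list alone, adjusted p = 0.795 with an estimated correlation). Of the type I interferon-stimulated genes 2 of 41 were called higher, Trim25 and Helz2 (camera adjusted p = 0.966, 1 over the list alone), and of the interferon gamma and MHC class I genes 1 of 27 (0.602, 1 over the list alone), which was Socs1 (1.54 ± 0.285 to 15.4 ± 3.66 CPM). Trim25 was not called without untreated Stat1-/- DF replicate 2 or 3 or treated replicate 3 (adjusted p = 0.295, 0.113 and 0.308, range over its alternatives 7.01e-11 to 0.308). Helz2 was not called without any one of the untreated (0.104 and 0.11) or treated (0.0968 and 0.0559) replicates 2 and 3 (range 1.06e-12 to 0.11). Irf1 stood at 18.1 ± 3.46 CPM untreated and 20.2 ± 4.83 CPM treated. The comparison called 3442 genes (2067 higher, 1375 lower) against 1002 with the culture as a block, 1552 with DF alone in the fit and 586 with limma on FPKM. Without untreated Stat1-/- DF replicate 2 or 3 it called 447 and 472, and without treated Stat1-/- DF replicate 2 or 3 it called 464 and 437.

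In Stat1+/- VSMC, PDGF-BB raised immediate early, feedback and cytokine signalling genes. Egr3 rose from 2.22 ± 0.002 to 132 ± 7.68 CPM (log2 fold change 5.89 ± 0.26, adjusted p = 1.2e-06), Arc from 1.42 ± 0.049 to 75.5 ± 27.7 CPM (5.73 ± 0.30, 2.87e-06) and Errfi1 from 31.5 ± 2.72 to 503 ± 37 CPM (4.00 ± 0.12, 5.38e-08). Cish, a feedback inhibitor of cytokine receptors, rose from 1.18 ± 0.292 to 47.6 ± 7.27 CPM and the cytokine gene Lif from 16.6 ± 0.3 to 90 ± 6.37 CPM. The zinc finger genes Zfp799 (9.32 ± 0.405 to 3.14 ± 0.144 CPM), Zfp763 and Zfp12 fell. Of 14477 genes, 196 rose and 84 fell (111 and 37 by at least 2 fold).

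Among the lists in Stat1+/- VSMC, 25 of 31 immediate early genes rose with 6 not called (camera adjusted p = 3.42e-187, 30 over the list alone), with Fosb (16.4 ± 2.6 to 375 ± 127 CPM) and Atf3 (9.1 ± 0.366 to 195 ± 68.7 CPM) among them. MAPK feedback inhibitors rose in 6 of 16 (1.52e-37, 11 over the list alone), including Dusp5 (5.74 ± 1.99 to 99.6 ± 18.6 CPM). Inflammatory genes rose in 5 of 22 (4.51e-13, 9 over the list alone, adjusted p = 0.104 with an estimated correlation), growth factor genes in 3 of 27 (4.54e-08, 8 over the list alone) and JAK-STAT genes in 4 of 19 (4.11e-09, 6 higher and 1 lower over the list alone). Sterol genes rose in 4 of 20 (3.71e-08, 4 over the list alone, adjusted p = 0.461 with an estimated correlation), Hmgcr from 88 ± 0.465 to 207 ± 7.06 CPM, and heat shock genes in 2 of 10 (8.09e-08, 3 over the list alone). The type I interferon list was called higher with 0 of 41 members called by edgeR (0.0174, 2 over the list alone, adjusted p = 0.999 with an estimated correlation), and the interferon gamma list with 1 of 27 (0.000763, 3 over the list alone, adjusted p = 0.802 with an estimated correlation). FoxO targets (0.182, blocked 0.0484, lower) and SRF and MRTF targets (0.2, blocked 0.00182, higher) were called with the block alone. The count of 280 called genes was 1315 (836 higher, 479 lower) with the culture as a block, 462 in DESeq2, 77 with VSMC alone in the fit and 183 with limma on FPKM. Without untreated Stat1+/- VSMC replicate 0 or 1 it was 144 and 138, and without treated Stat1+/- VSMC replicate 0 or 1 it was 157 and 162.

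Stat1-/- VSMC raised genes of the same lists. Egr3 rose from 1.19 ± 0.674 to 120 ± 33.1 CPM (log2 fold change 6.69 ± 0.29, adjusted p = 1.33e-06), Arc from 0.598 ± 0.038 to 59.6 ± 12.3 CPM (6.63 ± 0.33, 2.7e-06), Errfi1 from 27.2 ± 2.26 to 446 ± 11.8 CPM (4.03 ± 0.13, 5.19e-08) and Cish from 1.4 ± 0.445 to 37.5 ± 3.15 CPM. Zfp799 and Zfp607b fell, the latter from 16.3 ± 1.19 to 7.51 ± 0.245 CPM. In all 179 genes rose and 65 fell (107 and 38 by at least 2 fold). Immediate early genes rose in 24 of 31 (camera adjusted p = 9.16e-195, 30 over the list alone), MAPK feedback inhibitors in 5 of 16 (5.39e-35, 11 over the list alone), growth factor genes in 3 of 27 (1.11e-07, 4 over the list alone), JAK-STAT genes in 4 of 19 (1.16e-07, 7 higher and 1 lower over the list alone) and heat shock genes in 2 of 10 (1.55e-07, 3 over the list alone). Inflammatory genes rose in 4 of 22 (1.25e-13, 10 over the list alone, adjusted p = 0.104 with an estimated correlation) and sterol genes in 4 of 20 (7.63e-07, 4 over the list alone, adjusted p = 0.544 with an estimated correlation). Mitotic genes were called lower as a list with 0 of 20 members called by edgeR (0.0485, 0 over the list alone, adjusted p = 0.999 with an estimated correlation). The interferon gamma list was called higher with 1 of 27 members, Socs1 (0.0364, 1 over the list alone, adjusted p = 0.999 with an estimated correlation). With the culture as a block this call ended (adjusted p = 0.11). The type I interferon list was not called (0.858), and SRF and MRTF targets were called with the block alone (0.362, blocked 0.00608, higher). The count of 244 genes was 1215 (787 higher, 428 lower) with the culture as a block, 406 in DESeq2 and 69 with VSMC alone in the fit. It was 158 and 127 without untreated Stat1-/- VSMC replicate 2 or 3, and 130 without treated Stat1-/- VSMC replicate 3.

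The PDGF-BB responses of both genotypes overlapped. In DF 459 genes rose in both genotypes (27.1 by chance) and 337 fell in both (16.1), in VSMC 164 (2.42) and 44 (0.377), and 0 genes called in both genotypes changed in opposite directions. Between cell types, 172 genes rose and 79 fell in both Stat1+/- DF and VSMC, and 161 and 53 in both Stat1-/- DF and VSMC. Across all 4 comparisons 147 genes rose and 42 fell each time. These shared counts belong to the main fit. With VSMC alone in the fit 70 and 65 genes rose and 7 and 4 fell in Stat1+/- and Stat1-/- VSMC, so fewer could be shared. Across 14477 genes the log2 fold changes of both genotypes correlated at Pearson 0.52 (Spearman 0.537) in DF and 0.465 (0.371) in VSMC, and those of both cell types at 0.452 (0.442) in Stat1+/- and 0.377 (0.348) in Stat1-/- cells. With genes of at least 5 CPM alone these were 0.86, 0.833, 0.754 and 0.678. Without treated Stat1-/- VSMC replicate 3 the value of 0.377 was 0.248.

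**Figure D2:**
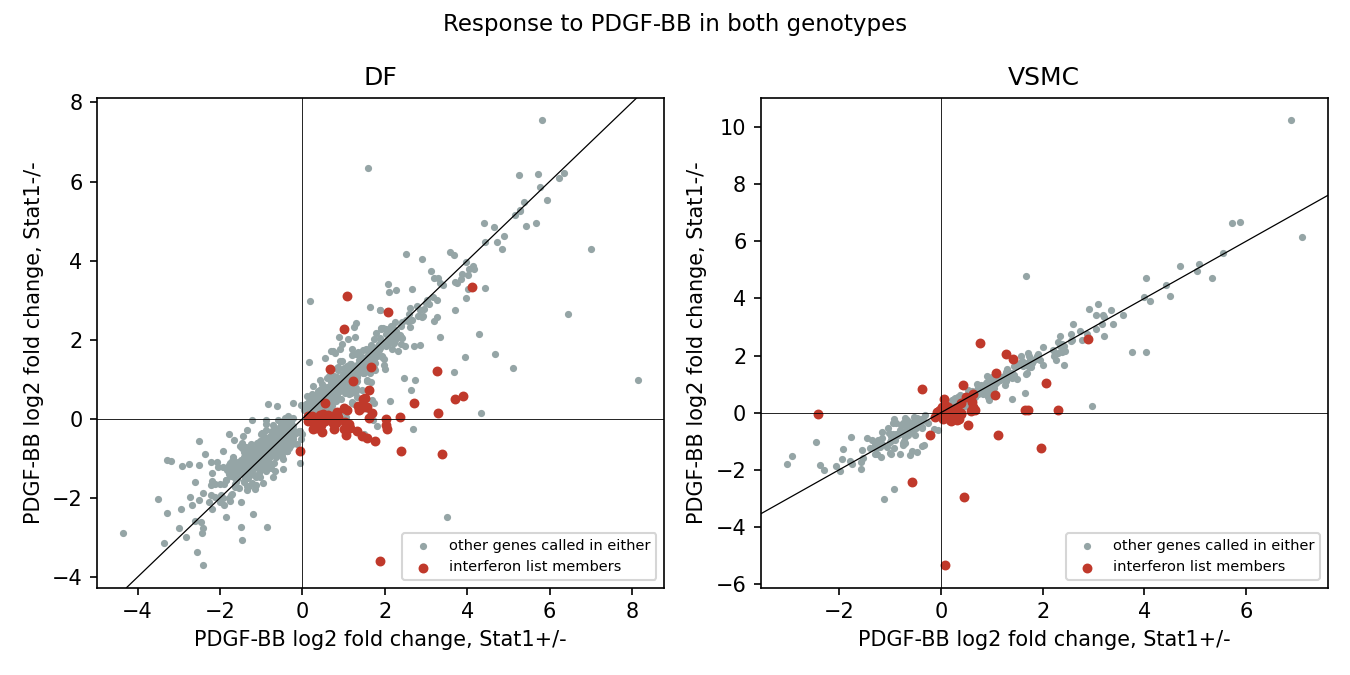
Log2 fold change with PDGF-BB in Stat1+/- cells (x axis) and in Stat1-/- cells (y axis), for each cell type, with genes called in either genotype in grey, members of both interferon lists in red, and the line of equal response. In DF the median fold of the interferon-type genes was 2.07 in Stat1+/- and 1.02 in Stat1-/- cells.

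The genotype by PDGF-BB interaction asks whether the response differed between genotypes. In DF, edgeR called 0 genes with the pairing of treated and untreated cultures left out (388 at an unadjusted p below 0.05). DESeq2, which left it out too, called 11, of which 10 had a lower response in Stat1-/- cells. As lists, interferon gamma and MHC class I genes (26 of 27 below 0, median -0.97, camera adjusted p = 3.18e-35, 0.0263 with an estimated correlation, 5 lower over the list alone) and type I interferon-stimulated genes (38 of 41 below 0, median -0.77, 5.67e-27, adjusted p = 0.158 with an estimated correlation, 0 over the list alone) responded less in Stat1-/- DF. The immunity GTPase gene Irgm1 (-2.05 ± 0.28, adjusted p = 0.112, blocked 4.34e-08, range over its alternatives 2.73e-08 to 0.901) and the antigen peptide transporter gene Tap1 (-1.12 ± 0.14, 0.109, blocked 4.06e-06, range 1.51e-07 to 0.901) had the smallest p-values of that list. Immediate early genes were called lower (median -0.17, 0.00665, adjusted p = 0.38 with an estimated correlation). Their summed CPM in treated DF overlapped, at 7531 and 7636 in Stat1+/- and 7767 and 7256 in Stat1-/- cells. Untreated sums were 2218 and 2609 against 2727 and 2747, lowest in Stat1+/- replicate 0. With the culture as a block 122 genes were called, 46 higher and 76 lower, and 29 of the 76 were among the 68 measured members of both interferon lists. Mitotic genes were called higher with the block alone (0.531, blocked 0.00587). Without treated Stat1+/- DF replicate 1 the unblocked fit called 4 genes.

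In VSMC the interaction called 0 genes in edgeR (158 at an unadjusted p below 0.05) and 0 in DESeq2. With the culture as a block it called 2, Malat1 (higher) and the interferon-stimulated gene Ifit1 (lower), which were named after their values were seen. The type I interferon list was called lower (median -0.26, 30 of 41 below 0, camera adjusted p = 9.16e-05, adjusted p = 0.92 with an estimated correlation), as were mitotic genes (median -0.28, 0.00153, adjusted p = 0.999 with an estimated correlation). FoxO targets were called higher (median 0.15, 0.0109, adjusted p = 0.196 with an estimated correlation). Over each of these lists alone 0 members were called in edgeR. The block alone called PDGF receptors and co-receptors (0.179, blocked 0.00255) and extracellular matrix genes (0.422, blocked 2.1e-05), both higher. It also called contractile markers (0.557, blocked 0.000219) and leukocyte markers (0.107, blocked 0.000175) higher. Leukocyte sums went from 686.8 to 446.8 CPM in Stat1+/- VSMC replicate 1, the largest change. They went from 237.6 to 245.7 in replicate 0, and from 135.8 to 154.4 and 251.5 to 225.3 in Stat1-/- replicates 2 and 3. Contractile sums went from 8658 to 8789 and 10400 to 10190 in Stat1+/- VSMC, and from 17450 to 17190 and 7331 to 7371 in Stat1-/- VSMC.

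Without PDGF-BB, Stat1-/- DF had lower levels of interferon-type genes than Stat1+/- DF. Usp18, the protease that removes ISG15 from proteins, stood at 0.048 ± 0.022 against 25.3 ± 8.56 CPM (adjusted p = 4.74e-05), Isg15 itself at 0.585 ± 0.196 against 45.2 ± 16 CPM (log2 difference -6.27 ± 0.75, adjusted p = 0.00663) and the immunity GTPase gene Igtp at 7.34 ± 0.775 against 75.1 ± 20.8 CPM (-3.35 ± 0.38, 0.00557). In all 48 genes were lower and 1 was higher. Type I interferon-stimulated genes were lower in 23 of 41 with 18 not called (camera adjusted p = 2.22e-212, 39 over the list alone), and interferon gamma and MHC class I genes in 5 of 27 with 22 not called (1.7e-57, 16 over the list alone). Schwann cell and melanocyte markers were lower as a list with 0 of 10 called by edgeR (8.91e-08, 5 over the list alone). Immediate early genes (0.0129), MAPK feedback inhibitors (0.00891) and mitotic genes (0.0455) were called higher as lists with 0 members called by edgeR, and these calls ended with an estimated correlation (adjusted p = 0.455, 0.0931 and 0.999 with an estimated correlation). Summed CPM of the mitotic genes was 404.6 and 702.9 in Stat1+/- replicates 0 and 1 and 701.2 and 549.6 in Stat1-/- replicates 2 and 3, so Stat1+/- replicate 0 stood apart. The 49 calls were 109 in DESeq2 and 92 with DF alone in the fit, and 12, 2 and 2 without untreated Stat1+/- DF replicate 0, untreated Stat1-/- DF replicate 2 or replicate 3. Without Stat1-/- replicate 2 or 3, Isg15 had adjusted p = 0.212 and 0.162 (range over its alternatives 2.74e-11 to 0.212) and Igtp 0.147 and 0.134 (1.67e-17 to 0.147), while Stat1 and Usp18 passed in every alternative.

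In PDGF-BB-treated DF the interferon-type genes were again lower in Stat1-/- cells. Iigp1 stood at 0.234 ± 0.061 against 224 ± 107 CPM (log2 difference -9.89 ± 0.80, adjusted p = 0.000187), the antiviral gene Ifit1 at 1.91 ± 0.498 against 514 ± 224 CPM (-8.06 ± 0.84, 0.000807), Rtp4 at 0.152 ± 0.079 against 49.6 ± 14.4 CPM (-8.33 ± 0.70, 0.000187) and the GTPase gene Gbp3 at 1.17 ± 0.189 against 42.5 ± 8 CPM (-5.17 ± 0.61, 0.00168). Mx2 was at 0.032 ± 0.045 against 59.2 ± 24.9 CPM. Type I interferon-stimulated genes were lower in 38 of 41 (camera adjusted p = 3.04e-220, 41 over the list alone) and interferon gamma and MHC class I genes in 22 of 27 (6.27e-111, 26 over the list alone). In all 130 genes were lower and 17 higher. Schwann cell and melanocyte markers were lower in 1 of 10, Ngfr (0.0154, 2 over the list alone, adjusted p = 0.38 with an estimated correlation), and mitotic genes were higher as a list with 0 of 20 called by edgeR (0.0154, adjusted p = 0.999 with an estimated correlation). Their summed CPM was 394.3 and 721.1 in Stat1+/- replicates 0 and 1 and 729.3 and 639.9 in Stat1-/- replicates 2 and 3, and replicate 0 again stood apart. The receptor gene Bmpr2 (adjusted p = 0.0484) and the transport gene Trak2 (0.0489), both higher, were the called genes within 10 Mb of Stat1, 2 of 91 against 139 of 14153 elsewhere (Fisher's exact p = 0.227, adjusted 0.908 over 4 comparisons). The 147 calls were 280 in DESeq2, 80 of them higher, and 306 with DF alone in the fit. They were 77, 64 and 61 without treated Stat1+/- DF replicate 0, treated Stat1-/- DF replicate 2 or replicate 3. Ngfr was not called without treated Stat1+/- DF replicate 0 or 1 (adjusted p = 0.187 and 0.0857) or treated Stat1-/- DF replicate 2 (0.403, range over its alternatives 0.0131 to 0.403).

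In untreated VSMC, Stat1-/- cells again had less of the interferon-type transcripts. Usp18 stood at 0.018 ± 0.025 against 14.2 ± 7.83 CPM (adjusted p = 0.000479), and Isg15 at 0.523 ± 0.622 against 29.1 ± 16.8 CPM (-5.70 ± 0.78, 0.0165). Cd2ap, which encodes an adaptor protein of the actin cytoskeleton, was at 11 ± 6.54 CPM in Stat1-/- against 0.073 ± 0.103 in Stat1+/- VSMC (7.18 ± 0.82, 0.00161). The matrix protein gene Smoc2 was at 105 ± 26.9 against 36.9 ± 2.36 CPM (1.51 ± 0.21, 0.0166). In all 43 genes were lower and 6 higher. Type I interferon-stimulated genes were lower in 16 of 41 (camera adjusted p = 7.79e-126, 36 over the list alone) and interferon gamma and MHC class I genes in 5 of 27 (8.94e-38, 17 over the list alone). Leukocyte markers were lower as a list in Stat1-/- VSMC with 0 of 11 called by edgeR (median -1.65, 8.75e-10, 8 lower over the list alone, adjusted p = 0.283 with an estimated correlation). Their summed CPM was 238 and 687 in the Stat1+/- and 136 and 251 in the Stat1-/- mice. Sterol genes were called higher (1.15e-09, 1 over the list alone, adjusted p = 0.38 with an estimated correlation), inflammatory genes lower (0.00289, adjusted p = 0.761 with an estimated correlation) and mitotic genes lower (0.0342, adjusted p = 0.999 with an estimated correlation), each with 0 members called by edgeR. Mitotic sums were 533.6 and 536.6 CPM in Stat1+/- and 361.1 and 541.2 in Stat1-/- replicates 2 and 3, with replicate 2 apart. Inflammatory sums were 2162 and 3085 in Stat1+/- replicates 0 and 1, with replicate 1 apart, and 2120 and 2248 in Stat1-/- VSMC. The 49 calls were 184 in DESeq2, 4 with VSMC alone in the fit (where of the genes named here Usp18 alone was called), 140 and 5 without untreated Stat1+/- VSMC replicate 0 or 1, and 6 and 8 without untreated Stat1-/- VSMC replicate 2 or 3. Isg15 was not called without Stat1+/- replicate 1 (adjusted p = 0.0863) or Stat1-/- replicate 2 or 3 (0.173 and 0.0943), nor Smoc2 without Stat1+/- replicate 1 (0.205) or Stat1-/- replicate 2 (0.154). Over all their alternatives the adjusted p ranged from 3.44e-09 to 0.273 for Isg15, 3.96e-10 to 0.14 for Cd2ap and 1.05e-08 to 0.261 for Smoc2.

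In PDGF-BB-treated VSMC the same gene groups were lower in Stat1-/- cells. Usp18 stood at 0.043 ± 0.061 against 19 ± 9.01 CPM (adjusted p = 0.000238), Ifit1 at 0.843 ± 0.768 against 139 ± 92.2 CPM (-7.33 ± 0.89, 0.00482) and Igtp at 3.02 ± 1.05 against 53.9 ± 22.7 CPM (-4.15 ± 0.42, 0.00244). Cd2ap was higher, at 13.2 ± 6.48 against 0.07 ± 0.1 CPM (7.39 ± 0.80, 0.000812). In all 58 genes were lower and 10 higher. Type I interferon-stimulated genes were lower in 22 of 41 (camera adjusted p = 2.93e-138, 37 over the list alone) and interferon gamma and MHC class I genes in 6 of 27 (1.01e-38, 18 over the list alone). Leukocyte markers were lower as a list with 0 of 11 called by edgeR (median -1.15, 1.45e-05, 0 over the list alone, adjusted p = 0.544 with an estimated correlation), with summed CPM of 246 and 447 against 154 and 225. Mitotic genes (2.14e-06), inflammatory genes (0.0181) and MAPK feedback inhibitors (0.0275) were called lower, and sterol genes (3.24e-07), FoxO targets (0.00112) and endothelial markers (0.0245) higher, each with 0 members called by edgeR. These 6 calls ended with an estimated correlation (adjusted p = 0.783, 0.876, 0.158, 0.534, 0.096 and 0.487 with an estimated correlation). Mitotic sums were 531.9 and 545.9 CPM in Stat1+/- against 316.2 and 438.7 in Stat1-/- replicates 2 and 3, lowest in replicate 2. Endothelial sums overlapped between genotypes (503.6 and 385.6 against 316.7 and 519.8). Over all 4 genotype comparisons 29 genes were lower and 1 higher in Stat1-/- cells each time, and 20 of the 29 were members of the interferon lists. The 29 belongs to the main fit. It cannot hold with VSMC alone in the fit, where treated VSMC gave 8 calls, nor without untreated Stat1-/- DF replicate 2 or 3, where Stat1 and Usp18 alone passed in untreated DF. The 68 calls were 210 in DESeq2, 8 with VSMC alone in the fit (where of the genes named here Usp18 alone was called), and 28, 8 and 37 without treated Stat1+/- VSMC replicate 1, treated Stat1-/- VSMC replicate 2 or replicate 3. Without Stat1-/- replicate 2, Ifit1 (-6.65, adjusted p = 0.107) and Igtp (-3.85, 0.0543) were not called. Over all their alternatives the adjusted p ranged from 2.14e-15 to 0.173 for Ifit1, 4.26e-25 to 0.0838 for Igtp and 5.18e-11 to 0.0803 for Cd2ap.

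**Figure D3:**
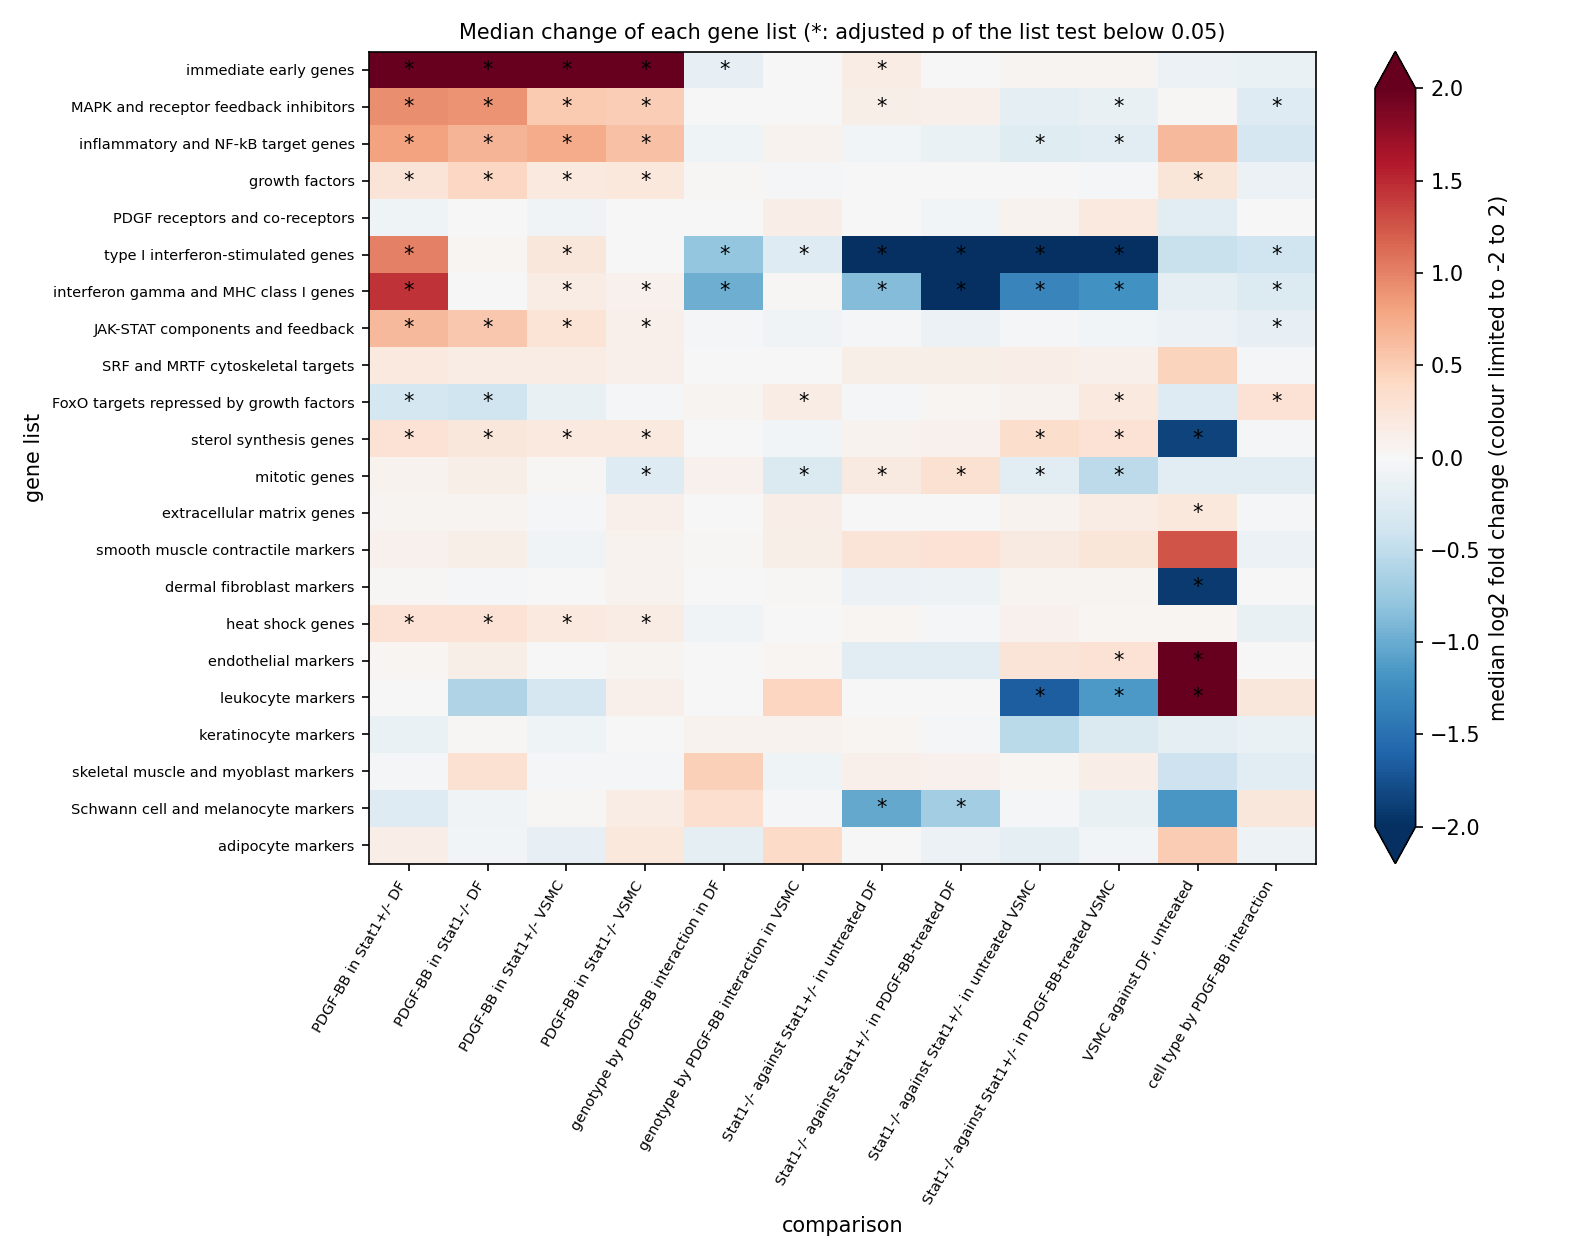
Median log2 fold change of the 22 gene lists (rows) in the 12 comparisons (columns), with colour limited to -2 to 2 and an asterisk where the camera adjusted p is below 0.05. The lists of interferon-type genes were lower in Stat1-/- cells in all 4 genotype comparisons, with medians of -2.92, -3.58, -2.22 and -2.67 for type I genes.

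Untreated VSMC and DF differed in 8506 of 14477 genes (58.8%), 4415 higher and 4091 lower in VSMC. Levels in this comparison are means of 4 mice per cell type. Myocd, the coactivator of smooth muscle genes, was at 7.31 ± 4.66 CPM in VSMC and 0.143 ± 0.081 in DF (log2 difference 5.64 ± 0.79, adjusted p = 0.000118), and the growth factor gene Bmp4 at 301 ± 76.3 against 0.351 ± 0.149 CPM (9.74 ± 0.38, 1.44e-08). Lum, a collagen-binding proteoglycan gene, was lower at 9.54 ± 13.5 against 277 ± 82.4 CPM (-5.35 ± 0.66, 6.12e-05), and the dermal transcription factor gene En1 at 1.4 ± 1.22 against 31.2 ± 2.18 CPM (-4.56 ± 0.42, 8.2e-06). Pdgfra was at 35.2 ± 11.8 against 390 ± 30.5 CPM (-3.47 ± 0.28, 2.97e-06) and Pdgfrb at 1041 ± 136 against 1107 ± 54.6 CPM (adjusted p = 0.395).

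Smooth muscle contractile markers were higher in VSMC in 14 of 18, lower in 1 and not called in 3, without a list call (camera adjusted p = 0.0501, 15 higher and 1 lower over the list alone). The member that was lower was Notch3, a receptor gene of smooth muscle and pericytes, at 0.089 ± 0.067 against 0.879 ± 0.2 CPM. The summed CPM of the contractile markers was 7331 in VSMC and 6292 in DF of replicate 3, and 8658 to 17450 against 4339 to 5094 in the other mice. Dermal fibroblast markers were lower in 13 of 18 with 5 not called (2.69e-12, 13 over the list alone), including Dpp4 (-3.01 ± 0.27). Sterol synthesis genes were lower in 20 of 20 (9.08e-27, 20 over the list alone, adjusted p = 0.0651 with an estimated correlation), among them Pcsk9, the regulator of the LDL receptor, at 3.34 ± 1.34 against 416 ± 73.3 CPM and Dhcr7 at 19.7 ± 5.37 against 154 ± 5.7 CPM. Growth factor genes were higher in 13 of 27 and lower in 6 (0.000191, 13 and 6 over the list alone), with Ngf at 138 ± 31.1 against 6.89 ± 1.46 CPM. Endothelial markers were higher in 10 of 12, lower in 1 and not called in 1 (1.04e-14, 10 higher and 2 lower over the list alone), with the endothelial receptor gene Tek lower (named after its values were seen) and the adhesion gene Pecam1 at 38 ± 5.92 against 0.159 ± 0.157 CPM. Leukocyte markers were higher in 11 of 11 (6.71e-09, 11 over the list alone, adjusted p = 0.363 with an estimated correlation), with the complement gene C1qb at 21 ± 17.5 against 0.049 ± 0.063 CPM.

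Extracellular matrix genes were higher in VSMC in 9 of 21, lower in 7 and not called in 5 (camera adjusted p = 0.00273, 9 and 7 over the list alone, adjusted p = 0.704 with an estimated correlation). Of those higher, Col1a1 (4972 ± 1141 CPM in VSMC), Col1a2, Col3a1 and Postn are listed at exactly 0 counts in all 8 DF libraries. The translation factor gene Eef1a1 and the matrix gene Thbs1 are also listed at 0 in DF, and the ubiquitin gene Ubc is listed at 0 in the 4 untreated DF libraries and at 289 ± 57.9 and 295 ± 41.6 CPM in treated Stat1+/- and Stat1-/- DF. Without these 7 genes the list pointed lower and was not called (adjusted p = 0.815). Keratinocyte markers were higher in 2 of 6 and lower in 2 (0.61), skeletal muscle and myoblast markers lower in 1 of 4 (0.922), Schwann cell and melanocyte markers higher in 2 and lower in 5 of 10 (0.943), and adipocyte markers higher in 2 and lower in 2 of 4 (0.956), without a list call. SRF and MRTF targets were higher in 8 and lower in 2 of 19 (0.208).

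The cell type by PDGF-BB interaction asks whether the response differed between VSMC and DF. It called 69 genes, 24 with a more positive and 45 with a more negative response in VSMC. Jak2, the kinase of cytokine receptors, rose in DF (log2 fold change 1.25 ± 0.09 in Stat1+/-, 1.27 ± 0.09 in Stat1-/-) and was not called in VSMC (0.18 ± 0.10 and 0.05 ± 0.10), a difference of -1.15 ± 0.09 (adjusted p = 0.000364). Nfkbia fell in DF (-1.20 ± 0.11 and -1.22 ± 0.11), against 0.25 ± 0.10 and 0.44 ± 0.10 in VSMC (1.55 ± 0.11, 0.000106). Rdh10, an enzyme of retinoic acid synthesis, rose more in DF (-1.64 ± 0.13, 0.00027), as did the MAPK phosphatase gene Dusp4 (-1.11 ± 0.11, 0.00128), Spred1, Nptx1, Gcc1, Taf4b, Fem1b and Mtcl1. MAPK feedback inhibitors responded less in VSMC as a list, 1 higher (Dusp7), 2 lower and 13 not called of 16 (camera adjusted p = 1.54e-05, 2 higher and 6 lower over the list alone), as did JAK-STAT genes, 2 lower and 17 not called of 19 (8.89e-05, 2 higher and 4 lower over the list alone, adjusted p = 0.0607 with an estimated correlation). FoxO targets had a more positive response in VSMC, with 1 of 15 called, Ccng2 (1.73e-07, 3 over the list alone). Both interferon lists were called lower with 0 members called by edgeR (4.59e-05 and 0.000215, adjusted p = 0.891 and 0.761 with an estimated correlation). Inflammatory genes (0.258, blocked 0.0203) and mitotic genes (0.208, blocked 0.00126) were called lower with the block alone.

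This interaction called 1320 genes (475 higher, 845 lower) with the culture as a block, DESeq2 called 216 and limma on FPKM 45. Each DF library moved the count of 69 by more than 1.5 times: it was 18, 21, 22 and 37 without untreated Stat1+/- DF replicates 0 and 1 and untreated Stat1-/- DF replicates 2 and 3, and 30, 36, 24 and 26 without the treated DF libraries of the same mice. It was 42 and 43 without untreated Stat1+/- VSMC replicate 0 or 1, 45 without untreated Stat1-/- VSMC replicate 2 and 45 without treated Stat1+/- VSMC replicate 0.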

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

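The tests of leukocyte markers and of expression by cell type in Ubc and in the 5 genes other than Postn were chosen only after the result was seen.

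The counts, genes and lists of this paragraph and the next stand here because a response to PDGF-BB differed between 2 groups of samples. The response differed between cell types in 69 genes (1320 with the culture as a block). Between genotypes edgeR called 0 genes in DF (388 at an unadjusted p below 0.05, 11 in DESeq2) and 0 in VSMC (158, and 0 in DESeq2), and with the culture as a block 122 and 2. Single genes, VSMC minus DF on the log2 scale, were Nfkbia (1.555), Rdh10 (-1.639), Jak2 (-1.146), Gcc1 (-1.091), Taf4b (-1.092), Dusp4 (-1.109), Nptx1 (-3.243), Fem1b (-0.6896) and Mtcl1 (-1.334). Ubc was fitted at -16, a value that depends on the prior count because Ubc is listed at 0 in untreated DF. No splits were made for the fit that gave the 69 genes. In another fit of this comparison, with the culture as a block and without genotype, the real split of the 8 cultures called 1014 genes. The highest of the other splits called 2 (1 of 35 splits gave as many). Untreated VSMC against DF is not a response to PDGF-BB and is given here for its splits. Its real split called 8457 genes and the highest other 29 (1 of 35). Each time 1 of 35 is the smallest share possible. Every other split puts both cell types in each arm, so that their difference adds to the spread. The gap in counts between the real and the other splits thus carries no weight of its own. The share of 1 of 35 argues against chance for the fits that were split but cannot exclude it. The real splits part the cells of all 4 mice, and the 7 other splits that do so called at most 2 and 0 genes. The split with 29 calls is the one by genotype.

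As lists, a smaller fold in Stat1-/- DF was called for immediate early genes (camera adjusted p = 0.00665, 0.38 with an estimated correlation). Their treated sums overlapped between genotypes, and their untreated sums were higher in Stat1-/- DF. Less response was also called for type I interferon-stimulated genes (5.67e-27, 0.158) and interferon gamma and MHC class I genes (3.18e-35, 0.0263). In VSMC the genotype lists were type I interferon-stimulated genes (9.16e-05, 0.92) and mitotic genes (0.00153, 0.999), both lower in Stat1-/- cells, and FoxO targets, which were higher (0.0109, 0.196). Between cell types, VSMC responded less in MAPK feedback inhibitors (1.54e-05, 0.0136), type I interferon-stimulated genes (4.59e-05, 0.891), interferon gamma and MHC class I genes (0.000215, 0.761) and JAK-STAT genes (8.89e-05, 0.0607), and had a more positive response in FoxO targets (1.73e-07, 0.0144), which in Stat1+/- VSMC were not called (0.182) but were called lower with the culture as a block (0.0484).

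Of 68 interferon-type genes, 29 were called higher with PDGF-BB in Stat1+/- DF (median fold 2.07, 67 above 1) and 3 in Stat1-/- DF (1.02, 37 above 1). Some, such as Ifit1 at 44 and 46 counts in untreated Stat1-/- DF, held few counts there, so their folds are imprecise. Irf1 held more, at 492 and 626 counts untreated and 681 and 526 treated. The rise of both lists in Stat1+/- DF was not called with an estimated correlation (adjusted p = 0.489 and 0.156). More leukocytes after PDGF-BB in the Stat1+/- cultures are argued against, since the summed CPM of 11 leukocyte markers changed 1.3 and 0.913 fold in the 2 mice, below the 2.07 fold they would need. No single library carries it: the median difference in response was -0.837, and nearest to 0, at -0.615, without treated Stat1+/- DF replicate 0. Leukocytes at a constant share that respond to PDGF-BB are hard to square with the sums but are not excluded: the 11 markers summed to 13.1 to 17 CPM in Stat1+/- DF, where the interferon sum went from 4003 to 8428 and from 3192 to 5865 CPM, and to 237.6 to 686.8 CPM in Stat1+/- VSMC, where it went from 3386 to 3693 and from 4222 to 4964 CPM, and no level of these genes in leukocytes was measured to set a share. A response that needs Stat1 may explain the pattern, but any difference between the mice other than Stat1 goes with genotype here and stays open, as do technical explanations not tested.

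Ubc belongs to a set of 7 abundant genes listed at exactly 0 counts in DF: Col1a1, Col1a2, Col3a1, Postn, Thbs1 and Eef1a1 in all 8 libraries and Ubc in the 4 untreated ones. Expression that differs by cell type may account for a low level of Postn, since Smoc1, at least as abundant in VSMC, is at 0.219 CPM in untreated DF. An exact 0 has no parallel among such genes, since 0 of 914 are at 0 there. Such expression is argued against for Ubc, at 285 CPM or more in both treated DF groups (without normalisation factors). For the 5 others it is undecided, since 7 other genes at most are as abundant in VSMC. The lowest of these 7 in untreated DF is Timp2, at 1640 CPM. Counts above a limit set to 0 were tested against the highest DF count of another row, 262370, and all 7 have VSMC counts below it, which had been meant to argue against a limit but was wrongly framed for the 6 genes without any DF count, whose level in DF is unknown and could exceed that in VSMC, so that a limit cannot be told apart from low expression for these 6. For Ubc that reason is weaker: its treated DF counts reach 9876, so a limit would need untreated counts above 262370. Counts or rows lost in making the table stay open for all 7 and for Fn1, which is listed at 0 in all 16 libraries, and were not tested, and their zeros are not read as absence of expression.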

How the results depend on the processing

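The tests with limma on log2(FPKM + 0.5) and without the 7 genes listed at 0 were chosen only after the result was seen. Of 502 values of named genes, 495 kept their direction and side of the threshold in DESeq2, 500 with RLE size factors, 487 with the legacy method, 489 without a filter and 458 with limma, as did 419 of 422 at a mean of at least 5 CPM, 269 of 350 with 1 cell type in the fit, 398 of 420 with the culture as a block, 482 of 490 without the genes at 0 and 2869 of 3360 with 1 library left out; 0 values called in either setting changed sign, while uncalled ones did. With 1 cell type in the fit, PDGF-BB changed 1890 and 1552 genes in Stat1+/- and Stat1-/- DF and 77 and 69 in VSMC, and genotype changed 92 and 306 in untreated and treated DF and 4 and 8 in VSMC. DESeq2 gave 462 and 406 for PDGF-BB in Stat1+/- and Stat1-/- VSMC, 109, 280, 184 and 210 for genotype in untreated and treated DF and VSMC, 11 for the genotype interaction in DF and 216 for the cell type interaction. A block for the culture let PDGF-BB change 4138, 3442, 1315 and 1215 genes, and the interactions 122 (DF), 2 (VSMC) and 1320 (cell type). Limma on FPKM gave 742 and 586 for DF, 183 for Stat1+/- VSMC and 45 for the cell type interaction. With an estimated correlation 35 of 78 list calls held. The extracellular matrix list between cell types reversed without the genes at 0 (adjusted p = 0.815), which by construction removes 4 of its higher members. Correlations between responses were 0.86, 0.833, 0.754 and 0.678 at a mean of at least 5 CPM, with fewer genes tested (10332). For the other changes the cause was not tested. The block ended 1 list call (interferon gamma genes in Stat1-/- VSMC) and 1 named call (Oasl2, VSMC against DF, where the block was the mouse). It made 20 named calls, turned the sign of 1 uncalled value (Pdgfra, PDGF-BB in Stat1-/- VSMC, 0.00644) and changed no other of the 420 named values. It also made 10 list calls (62 of 176). Leaving out 1 library, counts ranged for PDGF-BB in Stat1+/- DF from 570 (untreated replicate 0) to 773 (treated 1), Stat1-/- DF 437 (treated 3) to 472 (untreated 3), Stat1+/- VSMC 138 (untreated 1) to 162 (treated 1) and Stat1-/- VSMC 127 (untreated 3) to 204 (treated 2). For genotype they ranged in untreated DF from 2 (Stat1-/- 2 or 3) to 33 (Stat1+/- 1), treated DF 61 (Stat1-/- 3) to 125 (Stat1+/- 1), untreated VSMC 5 (Stat1+/- 1) to 140 (Stat1+/- 0) and treated VSMC 8 (Stat1-/- 2) to 82 (Stat1+/- 0). The genotype interaction in DF gave 0 to 4 (treated Stat1+/- DF 1), the cell type interaction 18 (untreated Stat1+/- DF 0) to 65 (treated Stat1-/- VSMC 3), and untreated VSMC against DF 7561 to 8153. The correlations ranged from 0.443 to 0.52 (genotypes, DF), 0.322 to 0.465 (genotypes, VSMC), 0.339 to 0.452 (cell types, Stat1+/-) and 0.248 to 0.378 (cell types, Stat1-/-). List tests were not rerun without single libraries. Depth limits genes of few counts: 19017 were tested without a filter.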

Other observations

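The pattern in zinc finger genes, and Apol9a, Apol9b, Rnf31 and Gpr137b-ps, were chosen only after the result was seen; the tests of abundance and length were written before their own results.

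Genes outside the interferon lists, Stat1 itself among them, were also lower in Stat1-/- cells in all 4 genotype comparisons. The lists need not hold every interferon-stimulated gene, so this does not show an effect beyond interferon signalling. Rnf31, a subunit of the linear ubiquitin ligase that acts in NF-kB signalling, stood at 26.1 ± 0.632 against 74.2 ± 5.59 CPM in untreated DF (log2 difference -1.50 ± 0.16, adjusted p = 0.00441) and at 22.5 ± 3.68 against 56.5 ± 7.56 CPM in untreated VSMC (-1.33 ± 0.17, 0.00798). The apolipoprotein L genes Apol9a (1.86 ± 0.2 against 8.63 ± 2.83 CPM in untreated DF, adjusted p = 0.0146) and Apol9b (0.988 ± 0.002 against 4.46 ± 0.565 CPM, 0.0346) were lower too. In untreated DF, Rnf31, Apol9a and Apol9b were not called without Stat1-/- replicate 2 or 3, since Stat1 and Usp18 were the only genes that still passed. Their fold changes without single libraries were not computed.

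Gpr137b, a lysosomal membrane protein gene, was higher in Stat1-/- cells, at 52.6 ± 4.3 against 36.8 ± 1.42 CPM in untreated DF (adjusted p = 0.102), 53.5 ± 3.48 against 34.1 ± 2.96 in treated DF (0.0122), 81.9 ± 3.06 against 50.7 ± 3.04 in untreated VSMC (0.0232) and 75.3 ± 6.46 against 49.5 ± 5.2 in treated VSMC (0.036). It was not called in treated DF without Stat1+/- replicate 1 (0.116) or Stat1-/- replicate 2 or 3 (0.177 and 0.0555). In VSMC it was not called without any one of the 4 libraries, untreated (0.0649, 0.119, 0.143 and 0.15) or treated (0.146, 0.0728, 0.105 and 0.18). The row of its pseudogene Gpr137b-ps, named after its values were seen, went the other way in all 4 comparisons, at 31 ± 2.66 against 49.1 ± 1.24 CPM in untreated DF (adjusted p = 0.0165) and 32.9 ± 2.23 against 54.3 ± 2.56 in untreated VSMC (0.0141). In untreated DF the row of Gpr137b-ps was not called without Stat1-/- replicate 2 or 3, since Stat1 and Usp18 alone still passed. Whether reads moved between the rows of Gpr137b and Gpr137b-ps was not tested.

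Zinc finger genes (350 tested, names starting with Zfp or Zkscan) fell with PDGF-BB more often than other genes. In Stat1+/- and Stat1-/- DF 41.4% and 34.9% of them were called lower, against 2.97% and 2.05% of other genes, and in VSMC 13.7% and 10% against 0.255% and 0.212%. With VSMC alone in the fit, 7 and 4 genes of any kind were called lower in Stat1+/- and Stat1-/- VSMC, so the VSMC shares depend on the fit. Low abundance alone is argued against, since the median of the zinc finger genes lay -0.375 (log2) from genes matched on abundance. Transcript length is argued against too, at -0.341 from genes matched on length and abundance. These lengths were computed back from the counts and the authors' FPKM, whose own lengths are not stated. Of the 42 genes lower in all 4 comparisons 29 were zinc finger genes, and without those the median of the zinc finger genes was -0.321. A fall of short-lived transcripts may explain this and was not tested, and reads shared between these related genes stay open.

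Summed CPM of contractile markers differed between the Stat1-/- VSMC cultures, at 17450 and 7331 untreated and 17190 and 7371 treated in mice 2 and 3, against 8658 and 10400 in untreated Stat1+/- VSMC. Schwann cell and melanocyte markers summed to 60.5 and 46 CPM in untreated Stat1+/- DF and 20 and 27.4 in Stat1-/- DF, with Ngfr at 29.3 ± 6.54 against 9 ± 4.57 CPM. The first principal component held 72.3% of the variance and separated the cell types, and the second held 6.9%. Every library had Y-linked transcripts (Uty 139.2 to 210.2 CPM, Kdm5d 24.7 to 35.8, Eif2s3y 72 to 90.8) and at most 6 counts of Xist.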
